A study of Homo sapiens with 8 samples.

How the data were processed

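Expression was measured in 8 samples of total RNA, isolated with RNeasy from 4 human neuroblastoma cell lines grown in RPMI medium and labelled as biotinylated cRNA with a 3' IVT Express kit, on an Affymetrix array with perfect-match probe sets. The deposited values are log2 signals made by the authors with RMA (robust multi-array average), per the submitters' processing notes, which give no software version. The scale was checked on the values, whose array medians lay between 3.47 and 3.52. No scaling was added, and raw array images were not used here.

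Of 54715 probe sets, 102 were array controls, 40920 carried exactly 1 gene symbol, 864 carried several and 12931 were left unnamed. Probe sets with 1 symbol covered 19774 genes, and each gene was represented by its brightest probe set over the 8 arrays. Genes with a mean level at or above the 40th percentile of probe set means (log2 3.208) were tested, which left 14517. Where several probe sets of a gene are counted below, only those that reach the same level are included.

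Samples were grouped by treatment and cell line as labelled. Vehicle and ciclopirox arrays were paired because they came from the same cell line. Pairing was checked once on the levels relative to the mean of the lines, with a Pearson r across genes of 0.898 in SK-N-AS, 0.867 in NB1691, 0.885 in SK-N-BE(2) and 0.817 in SK-N-AS/shHIF1A. Nothing in the labels says that arrays came from separate cultures, so p-values of genes measure the spread between these samples. With the preset correlation, camera sets a list's genes against all other genes. Its p-values measure a spread across genes and not between lines. The main comparison was a limma fit with the cell line as a block (3 residual and 2.98 prior degrees of freedom). Knockdown against parent was a contrast in the same kind of fit over all arrays. The difference in response by line origin compared the 4 changes, SK-N-AS-derived lines against NB1691 and SK-N-BE(2), and the origin comparison under vehicle compared the 4 vehicle arrays, with 2 residual degrees of freedom each. All tests were two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. An exact two-sided sign-flip test over 4 lines cannot go below p = 0.125, so none was used for calls.

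Before the data were examined, 27 gene lists were written, together with the grouping, the tests, the rule for named genes and the alternatives. Of 618 list entries, 580 matched a gene on the array. The lists with at least 5 tested members, 26 in number, were tested with camera at a preset correlation of 0.01, then with an estimated correlation and with fry, and the Schwann cell and glial list had fewer and was not tested. Each member was also tested with p-values adjusted over the list alone. The genes named were, in the main comparison, those past the test with the same sign in all lines (none passed), up to 3 members per list past the test over all genes or, where none passed, as in every list, the 2 with the largest change in size, and a fixed set around HIF, MYC, KDM4, iron and proliferation. In the knockdown and origin comparisons they were up to 8 genes each way past the test with the same sign in every pair of arrays, for the difference in response up to 5 each way, and within a line the 5 largest changes each way. CA9, a member of that fixed set, was not analysed here. Genes named outside the rule are said to have been chosen after their values were seen.

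Alternatives tried were no cell line block, leaving out each line or array, averaging SK-N-AS with its derivative, no filter, a 60th percentile filter, the mean of a gene's probe sets, centring arrays on their medians, quantile normalization, an intensity trend, array weights, every probe set tested alone, a threshold of 0.1, only the arrays of the compared lines, and the labelled Myc status as grouping. Chosen after seeing the data were the count of genes changed at least 2-fold the same way in all lines, with its alternatives, the list test for line origin, and the alternatives for the HIF-target difference between knockdown and parent.

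The fits were tested on simulated data, with 50 genes changed at each of 2-, 4-, 8- and 16-fold among 14517. Gene variances were drawn from the fitted prior, a choice made after a first simulation that had used each gene's moderated variance. For ciclopirox 46%, 90%, 94% and 100% of changed genes were recovered and 11 unchanged genes were called. These shares hold for a change of the same size in all 4 lines. Real changes could be less even, as for GDF15 (1.14 in SK-N-AS, 4.35 in NB1691, mean 3.09), which was not called. The shares therefore do not say how many uneven changes were missed. For the knockdown 10%, 68%, 92% and 98% were recovered with 3 unchanged called, and for the difference by origin 0%, 38%, 90% and 96% with 7. Under vehicle 0% were recovered at each fold. A simulated shift of 0.5 in the glycolysis list gave an adjusted p of 1.04e-18 with the preset and 0.134 with an estimated correlation, and 0 other lists were called by camera in limma. Genes were simulated as independent of each other. The simulation therefore cannot tell how often lists whose members move together are called wrongly with the preset correlation. Software was R 4.3.3, limma 3.58.1, Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.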

Results

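Total RNA from 4 human neuroblastoma cell lines was measured on 8 Affymetrix expression arrays, 1 array per line and treatment. Each line was treated for 48 h with vehicle or with 2.5 µM ciclopirox, an antifungal drug that chelates iron. The lines were SK-N-AS, NB1691, SK-N-BE(2) and SK-N-AS/shHIF1A, a derivative of SK-N-AS with a knockdown of HIF1A, the oxygen-regulated subunit of hypoxia-inducible factor 1. The labels call SK-N-AS a c-Myc line and the other 3 lines N-Myc lines, although SK-N-AS/shHIF1A derives from SK-N-AS. MYC, the gene of c-Myc, had log2 levels of 10.16 in SK-N-AS and 9.86 in SK-N-AS/shHIF1A under vehicle, against 2.70 in NB1691 and 2.66 in SK-N-BE(2). MYCN, the gene of N-Myc, had levels of 12.05 in NB1691 and 12.48 in SK-N-BE(2), 5.41 in SK-N-AS/shHIF1A and 2.77 in SK-N-AS. Lines were grouped by origin and not by the labelled status, a choice that did not rest on these levels. Array medians lay between 3.47 and 3.52 on the log2 scale. The number of arrays limits the precision, and the SK-N-AS-derived lines are not independent of each other. No array was repeated within a line and treatment, so every error given is a spread between lines or arrays.

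**Figure D1:**
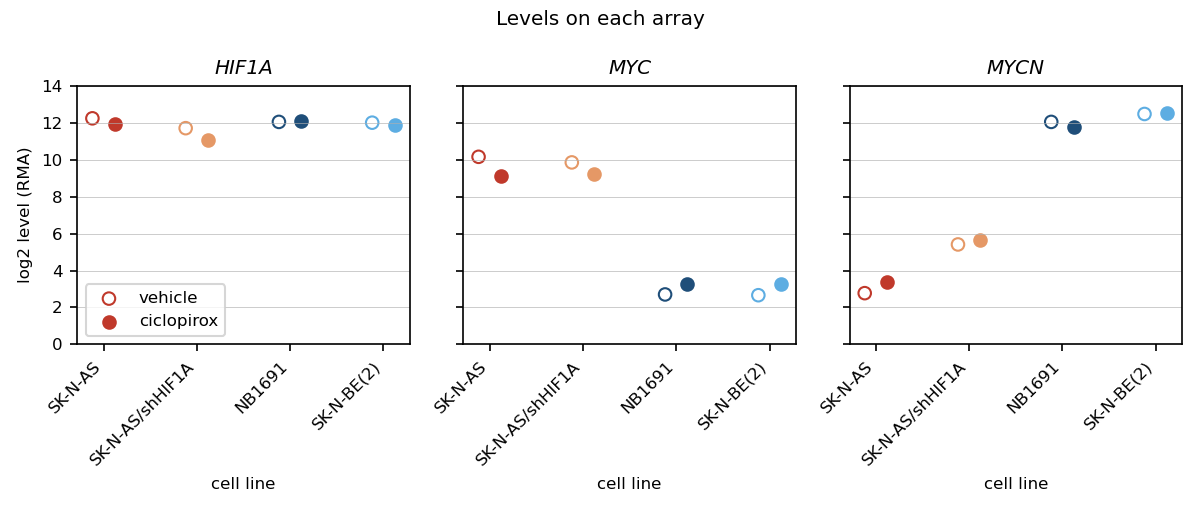
Log2 level (RMA) of HIF1A, MYC and MYCN on each of the 8 arrays, by cell line, with open circles for vehicle and filled circles for ciclopirox. Under vehicle MYC lies at 10.16 and 9.86 in the SK-N-AS-derived lines and MYCN at 12.05 and 12.48 in NB1691 and SK-N-BE(2).

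The main comparison asked which transcripts differed between ciclopirox and vehicle in lines labelled c-Myc or N-Myc, in a study whose title concerns Myc signalling and the histone demethylase JMJD2B, also called KDM4B. Targets of hypoxia-inducible factor rose together: of 39 tested, 27 rose and 0 fell when p-values were adjusted over the list alone, 29 were higher in all 4 lines, and the median log2 change was 1.13. BHLHE40, a transcriptional repressor, rose by 2.46 ± 0.31 (SE, n = 4 lines), and NDRG1, a stress-response gene, rose by 2.11 ± 0.34. VEGFA, the angiogenic growth factor, rose by 1.38 ± 0.27, with changes of 1.67 in SK-N-AS, 0.34 in NB1691, 1.79 in SK-N-BE(2) and 1.70 in SK-N-AS/shHIF1A. The low value in NB1691 belongs to the brightest VEGFA probe set, and the other 3 gave 0.90 to 1.41 there, with means over the lines of up to 2.14. EGLN3, a HIF prolyl hydroxylase, did not pass, with a mean change of -0.19. HIF1A itself had a mean change of -0.25 ± 0.15. EPAS1, another HIF subunit gene, had changes of 1.57 in SK-N-AS and 1.97 in SK-N-AS/shHIF1A, against -0.42 in NB1691 and -0.10 in SK-N-BE(2). Neither HIF1A nor EPAS1 passed over all genes. The list median was 1.67 in SK-N-AS, 0.38 in NB1691, 0.91 in SK-N-BE(2) and 0.97 in SK-N-AS/shHIF1A. The set test called the list higher (camera with a preset correlation, adjusted p = 1.04e-21), but not with an estimated correlation (adjusted p = 0.45 with an estimated correlation). With lines left out 1 at a time, 20 to 31 members passed, and without the cell line block 4 passed.

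Glycolysis genes were also called higher (median change 0.33, adjusted p = 3.29e-05, and adjusted p = 0.45 with an estimated correlation). Adjusted over the list alone, 6 of 17 rose and 0 fell, among them the neuronal enolase ENO2 by 1.52 ± 0.38 and the aldolase ALDOC by 1.49 ± 0.37 (SE, n = 4 lines). None of the 17 passed without SK-N-AS, without NB1691 or without SK-N-AS/shHIF1A (0 each in limma), and 6 passed without SK-N-BE(2). Among 25 other iron- and 2-oxoglutarate-dependent dioxygenases, 3 rose when adjusted over the list alone, including the collagen prolyl hydroxylases P4HA2 by 2.09 ± 0.28 and P4HA1 by 1.47 ± 0.25. Those genes also stand in the list of HIF targets. The dioxygenase list itself was not called (adjusted p = 0.0603, and adjusted p = 0.0173 without SK-N-AS/shHIF1A), and 0 members passed in limma without SK-N-AS. Of 23 histone demethylases, 1 rose when adjusted over the list alone, KDM3A, by 1.22 ± 0.13, which is a HIF target as well. JMJD6 had a mean change of 0.59 and did not pass, and 2 of its 3 probe sets had a positive mean change. KDM4B had changes of 0.66 in SK-N-AS, -0.10 in NB1691, 0.66 in SK-N-BE(2) and 0.09 in SK-N-AS/shHIF1A, with a mean of 0.33 ± 0.18. KDM4A and KDM4C had mean changes of 0.24 and 0.31. Of 5 KDM4B probe sets above the level filter 4 had a positive mean change, up to 0.50, and the other, at levels near 3.3, had -0.02. Further KDM4B probe sets below that filter, near background, were not counted. Of 4 KDM4C probe sets 3 had a positive mean change, and the lowest was -0.17. The histone demethylase list was not called (adjusted p = 0.119), and 2 members rose without NB1691.

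Iron handling genes moved in both directions: adjusted over the list alone, 4 of 20 rose and 2 fell. TFRC, the transferrin receptor that takes up iron, rose by 0.95 ± 0.13 and was higher in all 4 lines (0.76, 1.24, 0.78 and 1.02 in SK-N-AS, NB1691, SK-N-BE(2) and SK-N-AS/shHIF1A). SLC25A37, a mitochondrial iron importer, rose by 1.46 ± 0.31 (SE, n = 4 lines). The list was not called (adjusted p = 0.0535, and adjusted p = 0.542 with an estimated correlation), though it was called without SK-N-AS (adjusted p = 0.0299) and without SK-N-BE(2) (adjusted p = 0.0257). The number of rising members fell to 3 without SK-N-AS, 1 without NB1691, 2 without SK-N-BE(2) and 2 without SK-N-AS/shHIF1A, and 1 member fell in each of these fits.

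MYC targets in ribosome and nucleotide synthesis were called lower (median change -0.31, adjusted p = 2.4e-07, and adjusted p = 0.45 with an estimated correlation). Adjusted over the list alone, 7 of 44 fell and 0 rose, among them the ribosome assembly factors UTP20 by 0.82 ± 0.21 and NOP56 by 0.66 ± 0.12 (SE, n = 4 lines), and 20 were lower in all 4 lines. The list median was -0.47 in SK-N-AS, -0.16 in NB1691, -0.28 in SK-N-BE(2) and -0.23 in SK-N-AS/shHIF1A. The member count rests on all 4 lines: 0 members passed in limma without SK-N-AS, without NB1691, without SK-N-BE(2) or without SK-N-AS/shHIF1A. Of 13 MYC, MAX and MXD factors, adjusted over the list alone, MYCL fell by 1.38 ± 0.25 and MXD1, a MYC antagonist, rose by 1.09 ± 0.16, and 0 of them fell in limma without NB1691. That list was not called (adjusted p = 0.687), and its median was -0.02 while the test leaned higher. MYC had changes of -1.06 in SK-N-AS and -0.63 in SK-N-AS/shHIF1A, and 0.58 in NB1691 and 0.62 in SK-N-BE(2), where its levels lay near 3. MYCN had a mean change of 0.15 ± 0.17. The translation factor EIF5A had a mean change of -0.53 ± 0.13 and its hydroxylase DOHH one of 0.03 ± 0.20, and neither passed over all genes.

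Stress and growth-arrest lists were called higher. Of 23 p53 targets, 7 rose when adjusted over the list alone, including GDF15, a secreted stress cytokine, by 3.09 ± 0.56 and CDKN1A, the cell-cycle inhibitor p21, by 2.28 ± 0.34 (list median 0.52, adjusted p = 2.16e-05, and adjusted p = 0.45 with an estimated correlation). Without SK-N-AS, NB1691, SK-N-BE(2) or SK-N-AS/shHIF1A, 4, 4, 4 and 3 of them rose. The p53 list median was 1.12 in NB1691 and 0.21 to 0.23 in the other lines. Of 23 integrated stress response genes, 6 rose, including PPP1R15A, a phosphatase subunit, by 1.73 ± 0.21 and the transcription factor ATF3 by 1.04 ± 0.25 (list median 0.51, adjusted p = 2.42e-05, and adjusted p = 0.49 with an estimated correlation). The list median in SK-N-AS/shHIF1A was -0.06, and 1 member rose without SK-N-BE(2). Of 3 ATF3 probe sets 2 had a positive mean change, and the lowest was -0.11. Of 12 immediate early genes, 8 rose, including KLF4 by 1.82 ± 0.27 and FOS by 1.34 ± 0.26 (adjusted p = 1.08e-07, and adjusted p = 0.453 with an estimated correlation), with 3 rising without SK-N-AS and 4 without SK-N-AS/shHIF1A. Of 16 ER chaperones, 5 rose and 1 fell, with DNAJB9 up by 0.87 ± 0.17 and HERPUD1 by 0.70 ± 0.22 (adjusted p = 0.0076, and adjusted p = 0.49 with an estimated correlation). Without SK-N-AS 1 chaperone rose, 0 passed in limma without any of the other lines, and without NB1691 the chaperone call ended (adjusted p = 0.0976).

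Cell-cycle lists were called lower, with 0 members past limma when adjusted over the list alone. The median of 33 mitosis genes was 0.15 in SK-N-AS and 0.25 in NB1691, against -0.65 in SK-N-BE(2) and -0.73 in SK-N-AS/shHIF1A (adjusted p = 0.00786, and adjusted p = 0.773 with an estimated correlation). HMMR and CENPE had mean changes of -0.99 ± 0.28 and -0.74 ± 0.24. The mitosis call ended without SK-N-BE(2) (adjusted p = 0.435) and without SK-N-AS/shHIF1A (adjusted p = 0.472). The median of 39 DNA replication genes was -0.24, 0.30, -0.25 and -0.77 in SK-N-AS, NB1691, SK-N-BE(2) and SK-N-AS/shHIF1A (adjusted p = 0.00447, and adjusted p = 0.773 with an estimated correlation), and the call ended without SK-N-AS/shHIF1A (adjusted p = 0.549). The polymerase genes POLE2 and POLA1 had mean changes of -0.85 ± 0.25 and -0.80 ± 0.22. MKI67, a proliferation marker, had a mean change of 0.64 ± 0.29, with probe sets ranging from -0.51 to 0.64.

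Of the remaining lists, 4 were called, each with 0 members past limma when adjusted over the list alone. The mitochondrial respiratory chain (median -0.12, adjusted p = 0.0122, and 0.49 as the adjusted p with an estimated correlation) was lower, with SDHC at -0.45 ± 0.12 and NDUFS1 at -0.36 ± 0.12, for which 4 of 5 probe sets had a negative mean change. The noradrenergic identity list (median -0.34, adjusted p = 0.000816, and adjusted p = 0.504 with an estimated correlation) was lower, with the transcription factor ISL1 at -0.91 ± 0.28 and chromogranin CHGA at -0.81 ± 0.28, and SK-N-BE(2) had a list median of 0.10, without which 4 members fell. The BCL2 family (median 0.41, adjusted p = 0.000444, and adjusted p = 0.45 with an estimated correlation) was higher. In that family BCL2A1, which opposes cell death, had changes of 3.11 in SK-N-AS and 5.33 in SK-N-AS/shHIF1A against 0.08 in NB1691 and 0.03 in SK-N-BE(2). HRK, which promotes cell death, had changes of -0.08 and -0.99 against 2.67 and 2.08 in the same order. Mesenchymal markers (median 0.25, adjusted p = 0.0159, and adjusted p = 0.49 with an estimated correlation) were higher, with TGFBI at 1.47 ± 0.63 and AXL at 0.96 ± 0.27, but the call ended without SK-N-AS/shHIF1A (adjusted p = 0.211). TGFBI changed by 1.96 in SK-N-AS and 3.73 in SK-N-AS/shHIF1A, against 0.16 in NB1691 and 0.04 in SK-N-BE(2), where it lay near background. Without NB1691 2 mesenchymal markers rose, and without SK-N-BE(2) 1 rose and 1 fell.

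The other 9 lists were not called. In all, camera with the preset correlation called 13 of 26 lists, 8 higher and 5 lower, and 0 held with an estimated correlation in limma (smallest adjusted p 0.45). The test fry, which asks whether a list's genes move 1 way on balance and does not compare them with other genes, called 0 lists (smallest adjusted p 0.0967). Among cholesterol genes PMVK fell by 0.82 ± 0.13 when adjusted over the list alone, with DHCR7 at 0.47 (list adjusted p = 0.273), and the number falling was 1 without SK-N-AS, 2 without NB1691, and 0 in limma without SK-N-BE(2) or SK-N-AS/shHIF1A. Neuronal differentiation genes had adjusted p = 0.319, with STMN4 at 0.99 and NEFH at -0.84. NRF2 targets had adjusted p = 0.328, with AKR1C1 at 0.86 and HMOX1 at 0.48. Interferon genes had adjusted p = 0.0714 (0.0168 without SK-N-BE(2) and 0.0412 without SK-N-AS/shHIF1A), with IFIT3 at 0.99 and IRF7 at 0.66. Wnt targets had adjusted p = 0.687, with LGR5 at -0.58 and DKK1 at -0.57. Cytosolic ribosomal proteins had adjusted p = 0.932, with RPL23 at -0.72 and RPS23 at -0.06. Markers of other cell types were not called either: lymphoid and myeloid (adjusted p = 0.687, CD68 at 0.80, PTPRC at -1.09), epithelial (adjusted p = 0.471, KRT7 at 1.64, CLDN4 at 0.84) and endothelial (adjusted p = 0.721, EMCN at -0.91, PECAM1 at 0.46). Adjusted over the list alone, 1 of the 5 tested lymphoid and myeloid markers rose, CD68, and 1 fell, CORO1A, which is named after its values were seen. The count rising was 0 in limma without SK-N-AS, NB1691 or SK-N-AS/shHIF1A, and the count falling was 0 without NB1691, SK-N-BE(2) or SK-N-AS/shHIF1A. KRT7 changed by 2.13 in SK-N-AS and 4.55 in SK-N-AS/shHIF1A, against -0.02 in NB1691 and -0.08 in SK-N-BE(2). Without NB1691 1 epithelial marker rose. The epithelial median was -0.01 and its mean 0.44, and the endothelial median was 0.03 and its mean -0.03.

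**Figure D2:**
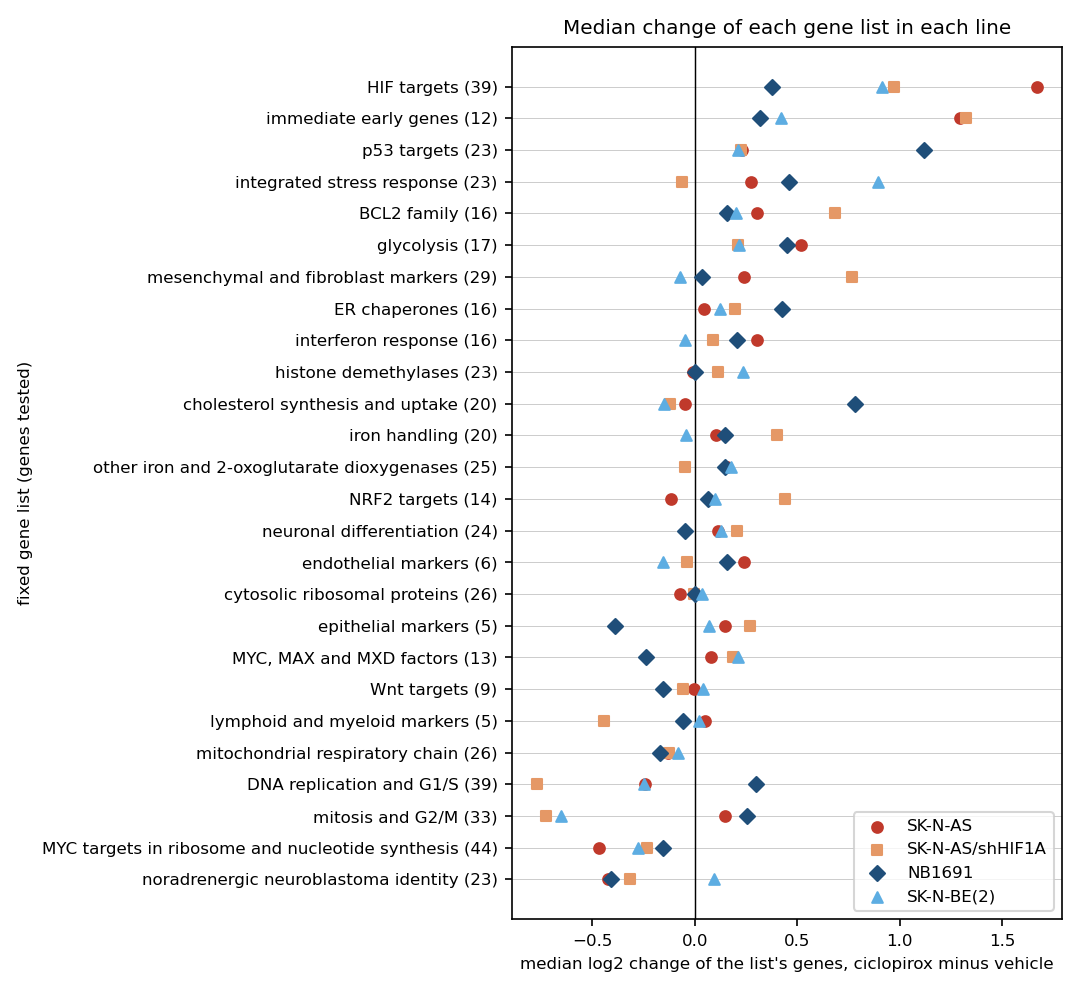
Median log2 change (ciclopirox minus vehicle) of each fixed gene list, 1 row per list with its number of tested genes in brackets and 1 point per cell line. HIF targets lie at 1.67 in SK-N-AS, 0.38 in NB1691, 0.91 in SK-N-BE(2) and 0.97 in SK-N-AS/shHIF1A, and p53 targets at 1.12 in NB1691 against 0.21 to 0.23 in the other lines.

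Over all 14517 genes tested, limma with cell line as a block called 0 genes at an adjusted p under 0.05 (smallest adjusted p 0.121), and 2599 genes (17.9%) had an unadjusted p under 0.05, 1113 higher and 1486 lower. As a description chosen after the values were seen, 24 genes changed at least 2-fold the same way in all 4 lines, 18 higher and 6 lower. The largest mean changes among them were GDF15 at 3.09, NEDD9, a focal adhesion scaffold, at 2.73 and STC1, a secreted glycoprotein, at 2.72, and at the other end VEGFD, a lymphangiogenic growth factor, at -2.08 and ARAP2 at -1.97. The count was 46 without SK-N-AS, 50 without NB1691, 79 without SK-N-BE(2) and 29 without SK-N-AS/shHIF1A. Leaving out a line asks for agreement in fewer lines.

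**Figure D3:**
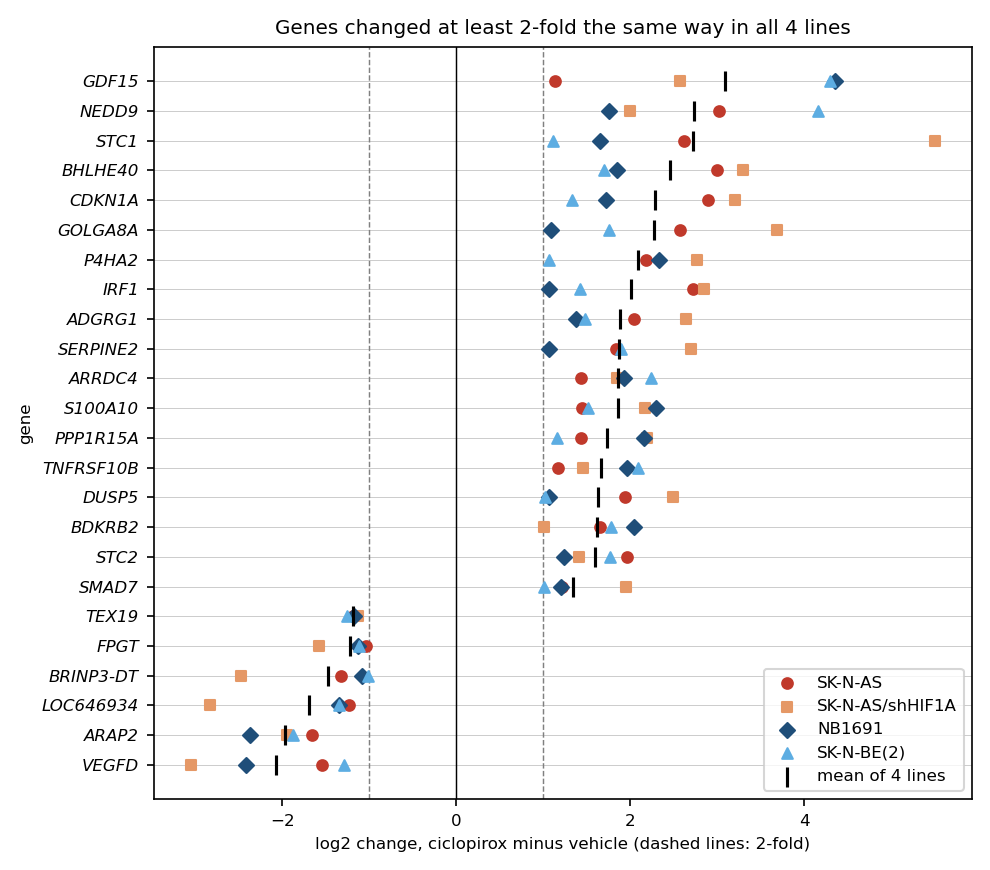
Log2 change (ciclopirox minus vehicle) of the 24 genes that changed at least 2-fold the same way in all 4 lines, with 1 point per cell line, a black tick for the mean of the lines and dashed lines at 2-fold. GDF15 ranges from 1.14 in SK-N-AS to 4.35 in NB1691, and 18 of the genes lie above 0.

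Within single lines the difference of 2 arrays carries no test, and the values are given as counts. At least 2-fold differences were found for 725 genes in SK-N-AS (490 higher, 235 lower), 1224 in NB1691 (481 higher, 743 lower), 487 in SK-N-BE(2) (306 higher, 181 lower) and 1427 in SK-N-AS/shHIF1A (802 higher, 625 lower). The largest increase in SK-N-AS was in the chemokine CCL20 (6.48), followed by CXCL8 (6.15) and CXCL10 (6.13), CEMIP (4.76) and COXFA4L3 (4.70). The largest decreases there were in TM4SF4 (-2.56), TAC1 (-2.19), RBM24 (-2.13), TRIL (-2.12) and PALMD (-2.10). NB1691 had RAB28P5 (4.61), GDF15 (4.35), CSTA (4.31), FITM1 (3.75) and GPNMB (3.60) at the top, and TM4SF4 (-3.70), PCP4 (-3.68), GPM6A (-3.17), DUXAP10 (-3.14) and SYCE1L (-2.83) at the bottom. SK-N-BE(2) had INHBE (6.04), GDF15 (4.29), NEDD9 (4.16), ATF5 (3.67) and SCRG1 (3.60) at the top, and OPN3 (-2.54), HPDL (-2.40), HTATIP2 (-2.32), RGS13 (-2.11) and QPCT (-2.03) at the bottom. SK-N-AS/shHIF1A had CCL20 (7.21), COXFA4L3 (6.43), CCL5 (6.34), IL11 (6.26) and CXCL8 (5.90) at the top, and TM4SF4 (-5.88), CALCB (-4.85), MRC1 (-4.69), FGFBP2 (-4.24) and PCDH20 (-4.06) at the bottom. Across genes, which are not independent replicates, changes in SK-N-AS and SK-N-AS/shHIF1A had a Pearson r of 0.69 (Spearman rho 0.59), and the other 5 pairs of lines had r between 0.185 and 0.253.

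The comparison of SK-N-AS/shHIF1A with its parent asked what the HIF1A knockdown line differed in. HIF1A had log2 levels of 11.71 and 11.09 in the knockdown under vehicle and ciclopirox, against 12.25 and 11.94 in the parent, a difference of -0.69 ± 0.21 (SE, 2 arrays per line, adjusted p = 0.257) that did not pass. Beyond HIF1A, 230 genes differed in limma (108 higher, 122 lower). POSTN, an extracellular matrix protein, was higher by 4.74 ± 0.28, followed by COL5A2 (4.69), ACKR3 (4.43), KYNU (4.42), YBX3 (4.30), MME (4.12), CD24 (4.04) and NRIP1 (3.99). GCG, the glucagon gene, was lower at -9.48 ± 0.20, followed by neuropeptide NPY (-7.91), S100A6 (-7.07), INSM2 (-6.46), the sympathoadrenal factor TFAP2B (-6.15), GSTP1 (-5.58), BCOR (-5.05) and UTS2 (-4.83). MYCN was higher by 2.47 ± 0.24 (adjusted p = 0.00928), at levels of 5.41 and 5.65. The count was 23 without the vehicle array of the parent, 28 without its ciclopirox array, 149 without the vehicle array of the knockdown and 162 without its ciclopirox array. COL5A2 (4.48 and 4.90), KYNU (3.88 and 4.96) and YBX3 (4.47 and 4.13) did not pass without the vehicle or the ciclopirox array of the parent, nor UTS2 (-4.95 and -4.71) without either array of the knockdown. The knockdown is 1 derivative, and its vehicle and ciclopirox arrays serve as its 2 values. The spread in this fit is how far changes under ciclopirox differ among the 4 lines. The p-values therefore measure no spread between independent knockdowns or repeated arrays.

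By list, 10 calls were made with the preset correlation, and 0 of them held with an estimated correlation in limma (smallest adjusted p = 0.663). Knockdown arrays were called higher for p53 targets (adjusted p = 0.0266), the integrated stress response (median 0.94, adjusted p = 1.78e-08), the BCL2 family (adjusted p = 0.0264), NRF2 targets (adjusted p = 0.0398) and endothelial markers (adjusted p = 0.0398). They were called lower for mitosis (median -0.61, adjusted p = 2.92e-08), glycolysis (median -0.41, adjusted p = 0.000279), DNA replication (adjusted p = 0.000771), HIF targets (median -0.34, adjusted p = 0.00849) and noradrenergic identity (adjusted p = 0.0489). The other 16 lists were not called. These calls take both treatments together, and some lists differed mainly under 1 of them. Median differences under vehicle and ciclopirox were -0.11 and 0.74 for NRF2 targets and -0.045 and 0.65 for the BCL2 family. They were -0.12 and -1.08 for mitosis, -0.009 and -0.55 for DNA replication, and -0.40 and -0.025 for noradrenergic identity. The integrated stress response differed under both (0.83 and 0.87).

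HIF targets changed less under ciclopirox in the knockdown than in the parent by value, with 1 array per line and treatment and no test: the median difference of the changes was -0.60, and 31 of 39 members were lower. Under vehicle the list differed by a median of -0.03 between the lines, and under ciclopirox by -0.67. Mitosis genes had a difference of changes of -0.97 and DNA replication genes one of -0.54, where the knockdown had the more negative list medians (-0.73 against 0.15, and -0.77 against -0.24). Some other list medians were smaller in size in the knockdown: MYC targets (-0.23 against -0.47), glycolysis (0.21 against 0.52) and the integrated stress response (-0.06 against 0.28). That of the BCL2 family was larger (0.68 against 0.31).

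**Figure D4:**
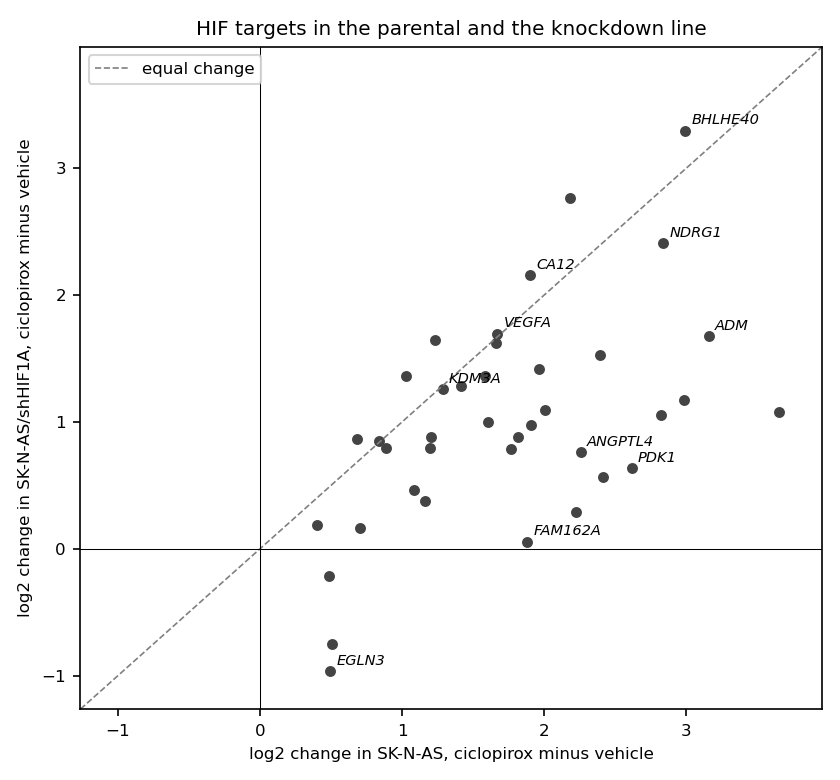
Log2 change (ciclopirox minus vehicle) of each of the 39 tested HIF targets in SK-N-AS on the horizontal axis and in SK-N-AS/shHIF1A on the vertical axis, 1 point per gene, with a dashed line of equal change and 10 genes named. Below the line lie 31 of the 39 genes.

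The difference in response by line origin asked whether the change under ciclopirox differed between the SK-N-AS-derived lines and NB1691 and SK-N-BE(2). It did for 5 genes in limma, all with larger changes in the SK-N-AS-derived lines: the chemokines CCL20 by 6.99 ± 0.32, CXCL8 by 6.28 ± 0.24 and CXCL11 by 4.44 ± 0.25, the hyaluronan-binding protein CEMIP by 4.80 ± 0.26, and the prostaglandin synthase PTGS2 by 3.52 ± 0.23 (SE, 2 lines against 2, adjusted p = 0.0114 to 0.0419). In NB1691 and SK-N-BE(2) the changes of these 5 genes lay between -0.27 and 0.25. With the labelled Myc status in place of the origin, limma called 0 genes. Without SK-N-AS, NB1691, SK-N-BE(2) or SK-N-AS/shHIF1A, limma called 0 genes each, with smallest adjusted p 0.0519, 0.225, 0.149 and 0.0751. The differences kept their size in these fits, from 6.63 to 7.35 for CCL20, 6.15 to 6.40 for CXCL8, 4.60 to 5.01 for CEMIP, 4.25 to 4.63 for CXCL11 and 3.44 to 3.60 for PTGS2. In all, 1643 genes had an unadjusted p under 0.05. Because the SK-N-AS-derived lines share an origin, errors and p-values here are too small for a statement about lines in general.

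Lists were also called by origin, in a test added after the data were seen. Values given are medians of the members' differences in change. The change was called more positive in the SK-N-AS-derived lines for HIF targets (0.44), immediate early genes (0.83), mesenchymal markers (0.48) and epithelial markers (0.62). It was called more negative or less positive there for DNA replication (-0.57), the integrated stress response (-0.68), cholesterol synthesis (-0.50) and noradrenergic identity (-0.30). Not all line medians lay apart by origin. DNA replication stood at -0.24 in SK-N-AS and -0.25 in SK-N-BE(2). Cholesterol genes were at 0.78 in NB1691 but -0.15 in SK-N-BE(2), below SK-N-AS (-0.05) and SK-N-AS/shHIF1A (-0.12). Noradrenergic identity was at -0.41 in NB1691, between SK-N-AS (-0.42) and SK-N-AS/shHIF1A (-0.31). The other called lists did lie apart, HIF targets narrowly (0.97 in SK-N-AS/shHIF1A, 0.91 in SK-N-BE(2)). With an estimated correlation 0 of the 8 calls remained (smallest adjusted p = 0.871), and the other 18 lists were not called.

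Under vehicle, the lines of the 2 origins differed in 243 genes in limma (153 higher and 90 lower in the SK-N-AS-derived lines). COL3A1, a fibrillar collagen, was higher by 9.59 ± 0.29, followed by TYRP1 (8.58), IFITM3 (8.33), CCL2 (8.19), TDO2 (8.05), CFI (8.02), CTAG2 (7.98) and PTX3 (7.95). ENPP2 was lower at -7.53 ± 0.29, followed by the RNA-binding protein LIN28B (-7.43), FABP6 (-7.19), TCEAL7 (-6.66), PAX5 (-6.36), NSG2 (-6.35), NUDT11 (-6.35) and KCNK3 (-6.14). The count was 0 without SK-N-AS and 0 without SK-N-AS/shHIF1A in limma, 645 without NB1691 and 1610 without SK-N-BE(2), against 2960 genes at an unadjusted p under 0.05 with all lines. Without NB1691, TCEAL7 (-6.29) and NSG2 (-6.50) did not pass either (adjusted p = 0.0543 each). With SK-N-AS or SK-N-AS/shHIF1A left out, 1 array stays on that side. The differences were then 9.78 and 9.40 for COL3A1 and -7.27 and -7.79 for ENPP2, in that order. The SK-N-AS-derived lines share an origin, so p-values of the vehicle comparison are too small for a statement about lines in general.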

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

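Tests of the MYCN, cytokine and HIF-target patterns and of the 2-fold count were chosen after their results were seen, whereas the swaps for genes and lists and the splits without the cell line block were chosen before.

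In 118 groups of 4 values, 1 per line, 8 had a line lying far from the other 3 by Dixon's criterion, which chance gives in about 1 of 20 groups. CD68 had a change of -0.16 in SK-N-BE(2) against 1.04 to 1.23 in the other lines. EMCN had -2.97 in SK-N-AS/shHIF1A against -0.31 to -0.07, and LOC646934, chosen after its values were seen, had -2.84 there against -1.35 to -1.24. STMN4 had 2.82 in NB1691 against 0.21 to 0.54, and VEGFA had 0.34 in NB1691 against 1.67 to 1.79. The VEGFA value rests on the brightest of 4 probe sets, and the other 3 gave 0.90 to 1.41 in NB1691. Among list medians, cholesterol genes had 0.78 in NB1691 against -0.15 to -0.05, p53 targets 1.12 in NB1691 against 0.21 to 0.23, and other dioxygenases -0.045 in SK-N-AS/shHIF1A against 0.15 to 0.18. No explanation was tested for these values.

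Changes under ciclopirox differed by line origin for 5 genes in limma: CCL20 (6.99), CXCL8 (6.28), CEMIP (4.80), CXCL11 (4.44) and PTGS2 (3.52). None of the 5 passed when any 1 line was left out (smallest adjusted p 0.0519 to 0.225), with fewer lines in the fit, but the differences stayed at 6.63 to 7.35, 6.15 to 6.40, 4.60 to 5.01, 4.25 to 4.63 and 3.44 to 3.60 in the same order. Lists were called as well, with a median difference in change of 0.44 for HIF targets, 0.83 for immediate early genes, 0.48 for mesenchymal markers, 0.62 for epithelial markers, -0.57 for DNA replication, -0.68 for the integrated stress response, -0.50 for cholesterol genes and -0.30 for noradrenergic identity. For DNA replication, cholesterol genes and noradrenergic identity the line medians did not lie apart by origin. With an estimated correlation the smallest adjusted p of these lists was 0.871.

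CCL20, CXCL8, CEMIP, CXCL11 and PTGS2 rose by at least 3.41 in each SK-N-AS-derived line. RNA from blood cells would bring other blood transcripts, but 11 lymphoid and myeloid markers had a median change of -0.036 over both lines (SD 0.859), from -3.23 (PTPRC, already high in these lines) to 1.23 (CD68). A shift of whole arrays would move all genes, and the median difference in change over all tested genes was -0.012 (SD 0.596). No such shift remained in the normalized values. Normalization had already brought the array medians to between 3.47 and 3.52, so this value cannot tell of a shift before it. A response that belongs to the SK-N-AS origin stays open, and with 1 origin on that side it was not tested against other c-Myc lines.

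MYCN was higher in SK-N-AS/shHIF1A than in SK-N-AS by 2.47. RNA of an N-Myc line could raise it, at shares of 0.62% to 1.15%, and would then raise 8 genes that are bright in such a line and dim in the parent by a median of 1.13 under vehicle. Their median rise was 0.29 under vehicle and 0.12 under ciclopirox (predicted 1.34), and 2 of the 8, INHBE and DCX, reached 50% of the prediction. These genes lie near the array floor in the parent and their rises spread widely (SD 2.13 under vehicle), so RNA of an N-Myc line stays open. An effect of the knockdown and a difference that arose as the derivative was grown were not tested.

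HIF targets had a smaller change under ciclopirox in the knockdown than in the parent, by -0.60. The SD of changes outside the list was 1.38 times that of the parent, so changes over all genes were not smaller. That SD includes changes of the derivative alone and the noise of single arrays. It cannot tell whether the part of the response that the lines share was weaker. A higher starting level of the list as a whole was not seen. Its median difference under vehicle was -0.032, on the lower side, against -0.67 under ciclopirox. With 1 array per line under vehicle and a wide spread of the members (SD 0.811), a higher start of single members stays open. The HIF1A knockdown itself may account for the difference, but there is 1 knockdown line, so it cannot be told apart from anything else in that derivative.

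Swapping the 2 arrays within lines gives 8 arrangements, too few for a share under 0.05. The real arrangement called 0 genes in limma (2599 at an unadjusted p under 0.05) and the highest other 0, so that 8 of 8 call as many by construction. For the count of genes changed at least 2-fold in all lines the real value was 24 and the highest other 2, with 1 of 8 as large. For lists the real value was 13 and the highest other also 13, with 2 of 8 as large. The lowest other value was 6. With the arrays of NB1691 swapped, HIF targets were still called (camera with the preset correlation, adjusted p = 7.08e-12). A call with the preset correlation therefore does not require that the lines agree. Without the cell line block, the real split called 0 genes in limma (451 at an unadjusted p under 0.05), so 35 of 35 splits of the 8 arrays call as many by construction, and this count says nothing about chance. The highest other split called 3621 genes. It separates the lines by origin and points to a structure of the samples.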

How the results depend on the processing

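The 2-fold count, the list test by origin and the HIF-target difference, with their alternatives, were chosen after seeing the data. The count of genes under ciclopirox stayed at 0 in limma under all 15 alternatives (smallest adjusted p 0.0682 to 0.899, the last without the cell line block, and 2599 genes at an unadjusted p under 0.05 in the reported fit). Lists called under ciclopirox numbered 12 to 15 with the preset correlation, 12 of them without the block.

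With an estimated correlation 0 lists were called for ciclopirox, 0 for the knockdown and 0 for origin, and HIF targets and MYC targets had an adjusted p of 0.45 each. With fry, which tests a list against no change and not against other genes, 0 lists were called, with 0.0967 for both. A correlation above the preset 0.01 widens the error. The estimate was 0.342 for HIF targets, 0.746 for DNA replication and 0.867 for mitosis genes, but 0.0186 for the BCL2 family and -0.148 for endothelial markers. In the simulation the shifted glycolysis list had an adjusted p of 0.134 in camera with an estimated correlation. A lost call is therefore no evidence against a shift, and its cause was not tested.

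HIF-target members past the test numbered 4 without the block. MYC-target members numbered 0 without the block, 0 to 0 when any 1 line was left out, 0 with SK-N-AS and its derivative averaged, 0 with the 60th percentile filter and 0 after quantile normalization, from 7 with list-alone p just under the threshold (0.0476).

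Genes differing in the knockdown numbered 23 to 162 when 1 of the 4 arrays was left out, where the lone array of a line is assumed to vary like the others, and 393 with only those arrays. The genes differing in response by origin numbered 0 to 0 without any 1 line, 0 with the labelled Myc status, 0 with an intensity trend and 9 with the mean of probe sets (4 shared), while without 1 line the differences of the 5 genes kept their size (CCL20 6.63 to 7.35). Under vehicle the origin count was 0 to 1610 without 1 line and 0 with the labelled Myc status. Fewer samples lowered the degrees of freedom, which does not account for counts that rose. Under vehicle, leaving out 1 line leaves a single array on its side, so the residual spread comes from the other side alone. Where that side was SK-N-AS and its derivative, with close vehicle arrays (r = 0.985), the count rose. Where it was the lines of the other origin (r = 0.949), the count fell. These vehicle counts therefore depend on which pair of arrays remains. The cause of the other moves was not tested.

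With the mean of probe sets, which averages in dim probe sets, genes changed at least 2-fold within a line numbered 483 in SK-N-AS, 767 in NB1691 and 277 in SK-N-BE(2), the HIF-target difference between knockdown and parent was -0.45, and 13 genes changed at least 2-fold in all lines. That last count was 137 at 1.5-fold, 29 to 79 without 1 line and 38 with SK-N-AS and its derivative averaged.

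No gene or list called in the reported fit or in the alternative changed direction. Of 885 values of named genes under ciclopirox, where none was called, 10 changed sign. Of 331 values of lists 31 became weaker, 15 stronger and 9 changed sign without a call in either fit. Of 288 member counts 58 moved. In the knockdown 9 of 184 gene values became weaker, by origin 31 of 54, and under vehicle 52 of 176. Signals near the background, such as MYCN at 2.77 in SK-N-AS, compress differences on arrays, so the sizes of changes there are not well measured.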

Other observations

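PTPRC, a leukocyte phosphatase, had log2 levels of 11.53 in SK-N-AS and 9.57 in SK-N-AS/shHIF1A under vehicle, against 3.12 in NB1691 and 3.22 in SK-N-BE(2). It was 10.42 and 6.34 in the SK-N-AS-derived lines under ciclopirox. MDM2, a ubiquitin ligase and p53 target chosen after its values were seen, had levels of 12.61 and 12.84 in NB1691 under vehicle and ciclopirox, against 8.29 to 8.93 on the other arrays. BCL2A1 reached 5.66 in SK-N-AS and 7.83 in SK-N-AS/shHIF1A under ciclopirox, from 2.55 and 2.50 under vehicle, and HRK reached 6.74 in NB1691 and 6.23 in SK-N-BE(2), from 4.07 and 4.15.

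Signals from the 3' and 5' ends of control transcripts serve as a measure of RNA integrity. The log2 difference between the ends lay between 0.11 and 0.27 for GAPDH over the 8 arrays. For ACTB it lay between 2.45 and 3.22, the highest in NB1691 under ciclopirox. The change of the GAPDH difference under ciclopirox was -0.03, -0.08, -0.06 and -0.11 in SK-N-AS, NB1691, SK-N-BE(2) and SK-N-AS/shHIF1A, and that of ACTB was 0.10, 0.40, -0.05 and -0.08.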
